A study of Homo sapiens with 6 samples.

How the data were processed

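Chromatin accessibility was measured by ATAC-seq (assay for transposase-accessible chromatin, in which a transposase inserts sequencing adapters into open DNA) in MDA-MB-231 cells, a triple-negative breast cancer line. The labels give 2 groups, empty vector (EV, 3 libraries) and knockdown of KDM2B by short hairpin RNA (shKDM2B, 3 libraries), and state that the libraries came from 3 biological replicates. The only comparison the labels imply is shKDM2B against EV. The replicate numbers do not say whether libraries of the same number were prepared together, so the groups were treated as unpaired and the number was tried as a block.

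The authors deposited 1 narrowPeak list per library on hg38. Per the submitters' processing notes, Trim Galore, Bowtie2 2.4.5, SAMtools 1.6, MACS2 2.2.7.1 and DiffBind were used; the notes give no settings, and whether reads were shifted for the transposase is not recorded. The fold values, as the authors deposited them, are a ratio of the fragment pileup at the summit to the local background of the same library. The −log10 p and −log10 q values, as deposited, belong to the summit of each peak within its own library, and the deposited score is a display score that was not used. The other deposited column used was the distance of the summit from the start of the peak. The weakest peak of each list had a −log10 p between 1.30 and 1.32, and the lowest −log10 q was 0, so the lists reach the threshold of 0.05 on p and are not limited by q. The authors' values are not normalised between libraries; they served here only to rank or filter peaks within a list and to describe a named peak, and the presence of peaks was compared between groups.

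The lists give no read counts, so the sequencing depth is unknown. The background coverage that each list implies was computed from its fold values, on the assumption that fold is (fragments + 1)/(background + 1): the 12 most frequent fold values gave the step of this grid. Between 47.3% and 55.3% of the peaks of a list then lay within 0.01 of a whole number of fragments, and for 97.7% to 98.5% of those a Poisson p from that background lay within 0.02 of the deposited −log10 p. The implied background was 2.05, 9.86 and 9.94 fragments per base in EV replicates 1, 2 and 3, and 7.55, 9.98 and 13.9 in shKDM2B replicates 1, 2 and 3. No counting interval per peak was computed, and replicate spread is the error given.

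Peaks on chromosomes 1 to 22 and X were used, and an interval listed for several summits counted once. Coordinates are 1-based on hg38. Gene positions came from a RefSeq table of GRCh38.p14 with 19970 protein-coding genes. This table holds gene starts and ends but no strand, transcripts or sequence, so the choices that had assumed transcription start sites were replaced: a gene boundary (either end of a gene) ± 1 kb stands in for a promoter, and the gene body ± 50 kb is called the domain of a gene. The annotation therefore separates gene boundary, gene body and intergenic sequence, but not exons, introns or UTRs. CpG content and motifs of the regions were not analysed, since the reference used here holds no sequence.

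Peaks of the 6 libraries that overlapped by at least 1 bp were merged into regions, and a region counted as called in a library that has a peak in it. Regions called in all 3 libraries of 1 group and in none of the other were counted, for the real groups and for the other splits of the 6 libraries into 3 and 3 (10 splits in all). Group means of values per library were compared by an exact permutation test, two-sided; with 3 libraries against 3 the smallest p it can give is 0.1. Similarity of 2 lists is the Jaccard index, the bases shared by both divided by the bases in either. Shares of regions were compared by Fisher's exact test, two-sided, with regions as the unit; regions are not independent replicates. Peaks per domain were tested by limma with an intensity trend on log2 of (peaks + 0.5), scaled to the library's total over all domains, for genes with a mean of at least 3 peaks. All adjusted p-values are by Benjamini-Hochberg, with a threshold of 0.05. Neighbouring genes share domains and are not independent.

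For 20 gene lists, written before the data were examined, members with a boundary called in 1 group only were compared with all genes whose boundaries were called in 1 to 5 libraries (Fisher's exact test), and peaks per domain were tested with limma's camera, at a preset correlation of 0.01 and at an estimated one. The lists were: serine, glycine and one-carbon metabolism; asparagine, aspartate, glutamate and proline metabolism; methionine cycle, transsulfuration and glutathione; amino acid transporters; aminoacyl-tRNA synthetases; purine and pyrimidine synthesis; ATF4 and integrated stress response; MYC and MYC targets; subunits of ncPRC1.1 (the polycomb complex of KDM2B); other polycomb and trithorax genes; developmental regulators often held by polycomb; epithelial-mesenchymal genes; cell cycle; hypoxia; AP-1, TEAD and YAP genes; inflammatory and interferon genes; housekeeping genes; and, as markers, luminal epithelial, immune, and fibroblast and endothelial genes.

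The rule for named genes was also fixed before the data were examined. It takes KDM2B; the 8 genes per direction with a boundary called in 1 group only, and the 5 other regions per direction, whose lowest percentile within the lists (by the authors' −log10 p, over the 3 libraries) is highest; by domain, the 6 with the largest fold past the threshold, or 3 per direction with the smallest p if none pass; and list members with a boundary called in 1 group only or among the 2 smallest p of their list. Genes named outside it are said to be chosen after their values were seen.

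Alternatives planned before the data were examined were a −log10 q of at least 5 (stricter threshold), the strongest 174172 peaks of each list (matched number, the length of the shortest), both thresholds at once (a region must pass the stricter one in 1 group and have no peak at all in the other), regions built from summits ± 100 bp, an overlap of 50%, all contigs, a window of 2.5 kb, a domain of 20 kb either side, an added constant of 2, no low-count filter, no scaling, the replicate block, and leaving out each library in turn. Chosen after the data were seen were the matched number within the stricter lists (124175 peaks), masking of the chromosome starts at which some libraries hold no peak, these together, leaving out each library under them, counting a boundary only where a region called in 1 group only lies there, and counting changed regions in gene domains.

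The steps were tested on simulated data first. Of 200 regions planted per direction among 318924, 200 and 200 were found, and the Jaccard index equalled that of bedtools 2.31.1 for 3 pairs of lists. The planted regions lay in gaps free of peaks and in every library of 1 group. Their recovery thus tests the set operations and not the sensitivity in real lists. In counts drawn from the real means of 18768 domains, limma recovered 43.3%, 82.1% and 95.5% of genes planted at 1.5, 2 and 3-fold among 200 changed genes, with 13 false calls, and made 1 call when nothing was planted. A list planted at a log2 shift of 0.5 reached an adjusted p of 5.44e-27 by camera, and 0 other lists were called. That shift is larger than the median log2 change of any list in the real data. The simulated genes varied independently, whereas real domains overlap. These rates of recovery and false calls need not hold in the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.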

Results

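KDM2B is a histone demethylase that also serves as the DNA-binding subunit of the polycomb complex ncPRC1.1. The series title places it in the control of amino acid metabolism together with MYC and ATF4. Open chromatin was mapped by ATAC-seq in MDA-MB-231 cells carrying an empty vector (EV, n = 3) or a short hairpin RNA against KDM2B (shKDM2B, n = 3), from 3 biological replicates. The lists of EV replicates 1, 2 and 3 held 215355, 191467 and 174172 peaks, and those of shKDM2B replicates 1, 2 and 3 held 184930, 231278 and 182542. Read depth is unknown, but EV replicate 1 stood apart: its implied background was 2.05 fragments per base against 7.55 to 13.9 in the other 5 libraries, and its median peak was 322 bp wide against 493 to 594 bp. In shKDM2B replicate 2 the authors' median fold over background was 2.86, against 4.79 to 5.25 in the others.

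**Figure D1:**
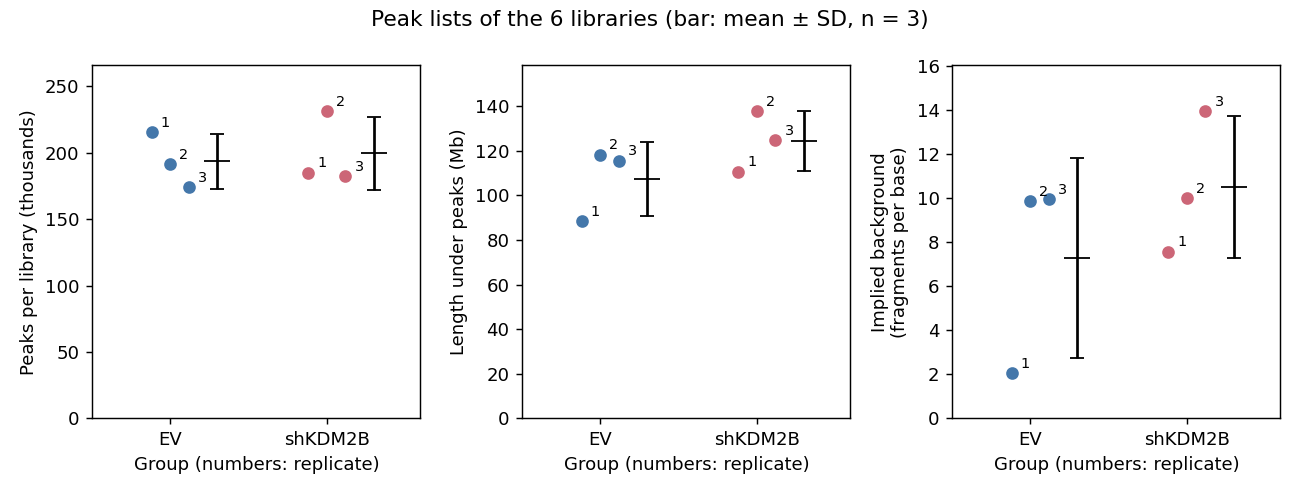
Peaks, length under peaks (Mb) and implied background (fragments per base) of each library, as points numbered by replicate, with group mean ± SD (n = 3). Peak numbers of the groups overlapped, and EV replicate 1 had both the shortest covered length (88.4 Mb) and the lowest background (2.05).

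The first question was whether the knockdown changed how much chromatin was open and where. The KDM2B gene itself (chromosome 12, 121408461 to 121582279) had a boundary called in all 6 libraries, and its domain held 54, 45 and 41 peaks in EV and 48, 57 and 41 in shKDM2B. Its log2 change in scaled peak number was 0.04 ± 0.09 (SE, n = 3 per group; limma adjusted p = 0.884), and −0.10 under the stricter threshold. These peaks do not measure the knockdown, because a hairpin RNA acts on the transcript. MYC (chromosome 8, 127735434 to 127742951) and ATF4 (chromosome 22, 39520559 to 39522686) also had boundaries called in all 6 libraries. Of the 19970 protein-coding genes, 76.4% ± 0.55 (SD, n = 3) had a called boundary in EV and 77.5% ± 1.67 in shKDM2B (exact permutation p = 0.5).

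Peak number averaged 193665 ± 20679 (SD, n = 3) in EV and 199583 ± 27474 in shKDM2B (exact permutation p = 0.7). Peaks covered 107.4 ± 16.5 Mb in EV and 124.3 ± 13.6 Mb in shKDM2B (exact permutation p = 0.3). Gene boundaries took 9.51% ± 0.32 of EV peaks and 8.80% ± 0.82 of shKDM2B peaks (exact permutation p = 0.3). Gene bodies took 45.4% and 45.8%, and intergenic sequence 45.1% and 45.4%. None of these differences passed the test, whose smallest possible p is 0.1, and the difference in peak number changed sign under the stricter threshold (shKDM2B minus EV −2361), without EV replicate 3 (−3828) and without shKDM2B replicate 2 (−9929).

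EV replicates 2 and 3 were the most similar pair of libraries, with a Jaccard index of 0.729. Pairs of shKDM2B libraries averaged 0.625 (0.585 to 0.681), and their pairs with EV replicates 2 and 3 averaged 0.624 (0.594 to 0.665). Under the stricter threshold these pairs separated, at 0.735 to 0.745 within shKDM2B and 0.676 to 0.720 between the groups. Pairs of EV replicate 1 with the other EV libraries reached 0.549, and its pairs with shKDM2B libraries 0.466 to 0.520. The mean Jaccard index within groups exceeded that between groups by 0.0354, the largest value of the 10 splits of the 6 libraries (next 0.0146; exact permutation p = 0.1, the smallest possible). Without EV replicate 1 the excess was 0.0270 and another split reached 0.0386 (exact permutation p = 0.2). Another split also exceeded the real one without EV replicate 2 (0.0480 against 0.0444) and without shKDM2B replicates 1 (0.0607 against 0.0287), 2 (0.0557 against 0.0310) and 3 (0.0469 against 0.0343).

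The next question was which individual regions were open in 1 group and not in the other. Near CCND1, the cyclin D1 gene, an intergenic region on chromosome 11 (69492453 to 69493095, 148 kb from the gene) was called in all 3 shKDM2B libraries, at the authors' fold of 3.05 to 4.68, and in no EV library. Other regions called only in shKDM2B lay in the body of the tumour suppressor gene MCC (chromosome 5, 113034373 to 113034810; fold 4.51 to 6.47) and 48.4 kb from SLC45A1 (chromosome 1, 8268944 to 8269719; 8.02 to 15.7). Further ones lay in the body of CCDC62 (chromosome 12, 122808666 to 122809283; 4.04 to 6.69) and 26.3 kb from ADD2, which encodes a membrane skeleton protein (chromosome 2, 70629865 to 70630483; 8.11 to 16.5). Regions called only in EV lay in the bodies of FAM53A (chromosome 4, 1581166 to 1581396; 7.94 to 15.5) and EHBP1 (chromosome 2, 62999817 to 63000564; 18.3 to 20.7). Others lay in the bodies of UQCC1, an assembly factor of respiratory complex III (chromosome 20, 35306830 to 35307383; 2.38 to 4.13) and the formin gene FHOD1 (chromosome 16, 67236476 to 67236809; 4.59 to 8.0). A further EV-only region lay 20.3 kb from UBE2F, a conjugating enzyme for NEDD8 (chromosome 2, 237945902 to 237946730; 14.5 to 20.5).

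Of 318524 merged regions, 117404 were called in all 6 libraries, 3420 in every EV and no shKDM2B library, and 4841 in every shKDM2B and no EV library. The 8261 regions called in 1 group only compare with at most 3882 in any other split of the libraries, the one that sets EV replicate 1 with shKDM2B replicates 1 and 3. Presence or absence of a peak in 3 libraries against 3 cannot pass a threshold of 0.05 for a single region (smallest p of Fisher's exact test 0.1), so no p is given per region. Requiring the stricter threshold in 1 group and no peak at all in the other left 1402 EV-only and 1471 shKDM2B-only regions. Leaving out a library loosens the requirement: without EV replicates 1, 2 and 3 the counts were 6080 and 7457, 5127 and 6905, and 6476 and 6029, and without shKDM2B replicates 1, 2 and 3 they were 4239 and 7632, 6747 and 8356, and 5226 and 8825 (EV only, then shKDM2B only). The larger number for shKDM2B thus turned around without EV replicate 3. With 2 libraries against 3 the requirement loosens unequally for the EV-only and shKDM2B-only counts. These counts are therefore not like those of 3 against 3, and do not by themselves test the direction.

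**Figure D2:**
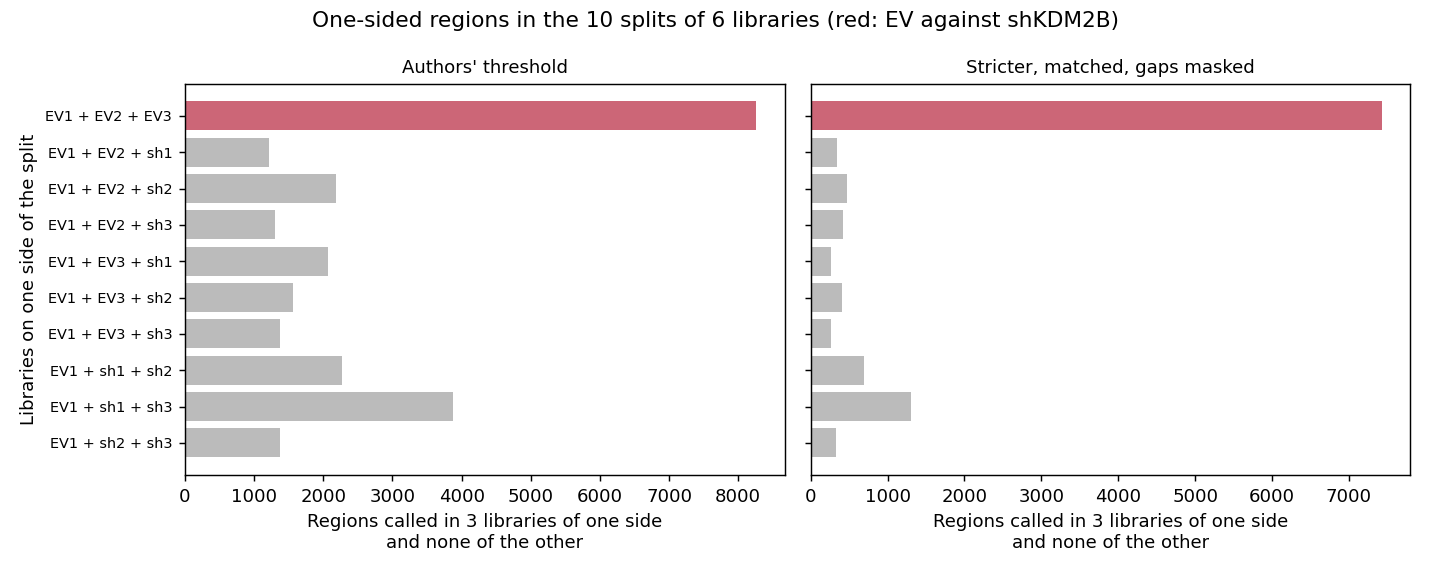
Number of regions called in 3 libraries of one side and none of the other (horizontal axis), for each of the 10 splits of the 6 libraries (vertical axis), at the authors' threshold (left) and with the stricter threshold, matched number and masked chromosome starts (right). The bar of EV against shKDM2B (red) reached 8261 and 7430, against at most 3882 and 1304 for the other splits (grey).

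Regions called in 1 group only lay mostly away from gene boundaries. Boundaries held 5.50% of EV-only regions (188 of 3420), 3.61% of shKDM2B-only regions (175 of 4841) and 13.96% of the regions called in all 6 libraries (16386 of 117404). The EV-only share exceeded the shKDM2B-only share (Fisher's exact test over regions, adjusted p = 0.000112). Gene bodies held 49.4% of shKDM2B-only and 45.0% of EV-only regions (adjusted p = 0.000155), and intergenic sequence 47.0% and 49.5% (adjusted p = 0.0300). Against regions called in 2 to 4 libraries in other patterns, of which 4.51% lay at boundaries, the EV-only share was higher (adjusted p = 0.0111) and the shKDM2B-only share lower (adjusted p = 0.00490). These tests take regions as the unit and do not measure the spread between libraries. Per library, the boundary share of all peaks did not pass the test (exact permutation p = 0.3). Median widths also differed and were not adjusted for: 395 bp for EV-only, 506 bp for shKDM2B-only, 887 bp for all 6 and 441 bp for 2 to 4 libraries.

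The direction of the regions called in 1 group only varied by chromosome. On chromosome 3, 517 regions were called only in shKDM2B and 191 only in EV, so 73.0% were shKDM2B-only, against 57.2% on all other chromosomes (Fisher's exact test over regions, adjusted p = 2.11e-15). On the X chromosome the numbers were 75 and 144, a share of 34.2% (adjusted p = 3.14e-12). The excess on chromosome 3 was spread along it: 15 of its 19 bins of 10 Mb lay above the genome's share of 58.6%, and 0 of 13 bins on X did. Chromosomes 1 (65.5%) and 2 (63.0%) also had higher shares, and chromosomes 9 (51.3%), 10 (52.2%), 13 (44.5%), 16 (45.1%) and 19 (47.8%) lower ones, at adjusted p from 0.000203 to 0.0408. The Fisher tests take regions as the unit and do not measure the spread between libraries. Of all peaks, 7.38% ± 0.25 (SD, n = 3) lay on chromosome 3 in EV and 8.12% ± 0.58 in shKDM2B (exact permutation p = 0.1). On X the shares were 2.14% ± 0.06 in EV and 1.90% ± 0.24 in shKDM2B (exact permutation p = 0.2). With the stricter threshold and matched number and without shKDM2B replicate 2, the X chromosome no longer differed (55.6% against 60.2% elsewhere; Fisher's exact p = 0.113).

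**Figure D3:**
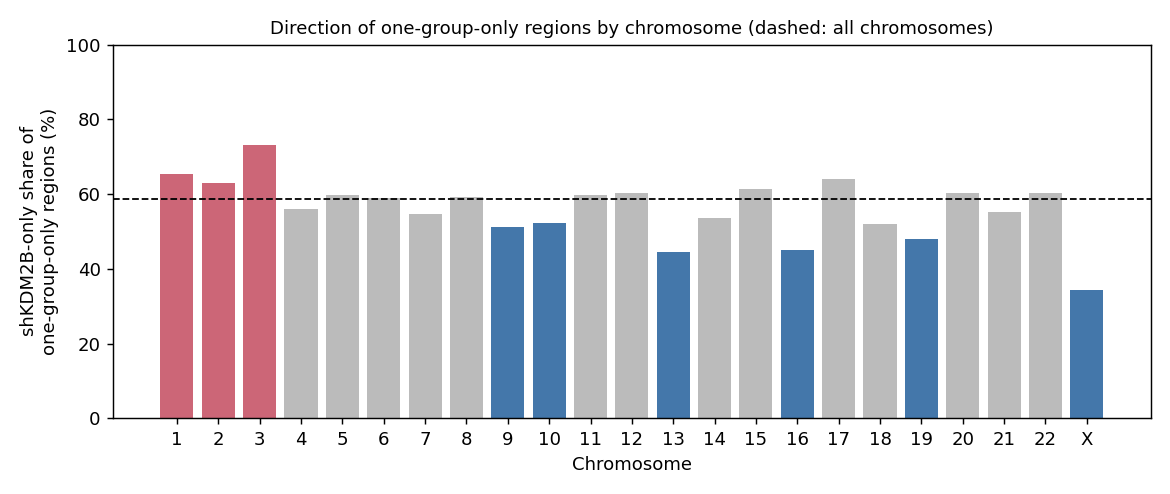
Share of the regions called in 1 group only that were called in shKDM2B (percent, vertical axis), per chromosome (horizontal axis), with the genome's share (58.6%) as a dashed line. Red and blue bars passed the adjusted Fisher test above and below it; chromosome 3 (73.0%) and X (34.2%) were the farthest from the line.

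At gene boundaries, TRAPPC3, a subunit of a vesicle tethering complex, had a region called only in EV (chromosome 1, 36136511 to 36137002; the authors' fold 5.80 to 10.2). KLHL30 (chromosome 2, 238138388 to 238139055; 4.38 to 7.14) and UQCRC1, a core subunit of respiratory complex III (chromosome 3, 48598382 to 48598860; 2.53 to 3.48), had one called only in shKDM2B. In all, 162 genes had a boundary window with a peak in every EV and no shKDM2B library, and 152 had the reverse (312 genes in either direction, against at most 154 in any other split). The strongest EV-only windows were at PPP1R14B, a phosphatase inhibitor, the ribosomal protein genes RPL35 and RPS12, WDR38, SIL1, ACMSD, TRAPPC3 and LILRB5. The strongest shKDM2B-only windows were at NFRKB, a subunit of the INO80 remodelling complex, LY9, TNNI3, HCN4, ZSWIM4, KLHL30, UQCRC1 and the DNA glycosylase gene MBD4. The other boundary of these genes was called in all 6 libraries, except at ACMSD (0), LILRB5 (4), LY9 (2) and TNNI3 (5). Without strand, the changed end need not be the promoter. With the 2.5 kb window only ACMSD kept a window called in 1 group only. With the summit rule only TRAPPC3, KLHL30 and UQCRC1 did. Of these 16 genes, 4 (TRAPPC3, ZSWIM4, KLHL30 and UQCRC1) had a region called in 1 group only at the boundary. At ZSWIM4 this region (fold 1.62 to 2.22) was not the peak that ranked the gene (3.70 to 4.99), which both groups had within 2.5 kb of the boundary. At the other 12, the merged region that reached into the window also held a peak of the other group outside it, so that no opening or closing of a region is shown there.

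A region called in 1 group only lay at a boundary of 210 genes for EV and 183 for shKDM2B (389 in either direction). The genes named next are among the 10 strongest per direction and were chosen after their values were seen. For EV they included TRNAU1AP, which acts in selenoprotein synthesis (chromosome 1, 28576804 to 28578278; fold 2.87 to 4.77), FXYD3 and LGI4 at 1 shared region (chromosome 19, 35123446 to 35123842; 5.06 to 11.1), and IKZF5 and PSTK, a kinase of selenocysteine synthesis, at another (chromosome 10, 122990334 to 122990611; 7.46 to 9.19). For shKDM2B, after KLHL30 and UQCRC1, the strongest were PRR36, EXOC3L2, ANXA8L1 and CDV3 (lowest percentile within the lists 68.6 to 62.3), followed by ABCC3, a drug and bile salt exporter (chromosome 17, 50634530 to 50634832; 1.68 to 2.44), HLA-DPA1 (chromosome 6, 33064670 to 33065487; 3.74 to 10.3) and SPP1, which encodes osteopontin (chromosome 4, 87982550 to 87982803; 3.75 to 4.83). Windows called in 1 group only numbered 103 genes when both thresholds were required, and without EV replicates 1 and 2 or shKDM2B replicates 2 and 3 they numbered 524, 475, 554 and 526.

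The same comparison was then made by the number of peaks around each gene. The domain of HRG, which encodes a plasma glycoprotein, held 8, 7 and 6 peaks in EV and 21, 22 and 14 in shKDM2B (log2 change 1.34 ± 0.15 SE, n = 3 per group; limma adjusted p = 0.0925). TRIM71, an RNA-binding ubiquitin ligase, had 18, 16 and 15 against 28, 32 and 26 peaks (log2 0.77), and CYP8B1, an enzyme of bile acid synthesis, 11, 10 and 8 against 18, 24 and 17 (log2 0.96). HRG, TRIM71 and CYP8B1 all lie on chromosome 3. So did 22 of the 50 genes with the smallest p among those with more peaks, against 1052 of all 18768 genes tested. The change at single genes was not tested apart from that of the chromosome. Fewer peaks in shKDM2B were counted around VWA1, a matrix protein gene (35, 25 and 25 against 13, 15 and 16; log2 −0.93; adjusted p = 0.0925), its neighbour LOC107985729 (log2 −0.81) and PRKDC, the catalytic subunit of DNA-dependent protein kinase (41, 31 and 31 against 20, 25 and 22; log2 −0.62; adjusted p = 0.108). All 6 missed the threshold: limma called 0 of 18768 genes, with 1251 genes with more and 1332 with fewer peaks at an unadjusted p under 0.05. Under the stricter threshold the log2 changes were 0.31 for HRG, 0.26 for TRIM71, 0.37 for CYP8B1, −0.76 for VWA1, −0.69 for LOC107985729 and −0.23 for PRKDC.

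Under the stricter threshold, limma called 2 genes with more peaks in shKDM2B (RCSD1 and TOPAZ1) and 7 with fewer (KLRG1, GPR26, SCX, BOP1, JAKMIP1, FBXL7 and VWA1), all at an adjusted p of 0.0457. These 9 genes were named after their values were seen. BOP1, a ribosome assembly factor on the MYC list, had 23, 24 and 22 strict peaks in EV and 13, 14 and 16 in shKDM2B (log2 −0.63 ± 0.07 SE), and its neighbour SCX had 20, 21 and 19 against 11, 12 and 13. RCSD1 had 14, 14 and 14 against 21, 19 and 22. Under that threshold, limma called 46 genes with more and 73 with fewer peaks without EV replicate 1, and 0 genes when any of the other 5 libraries was left out (909 to 1397 with more and 960 to 1360 with fewer at an unadjusted p under 0.05).

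**Figure D4:**
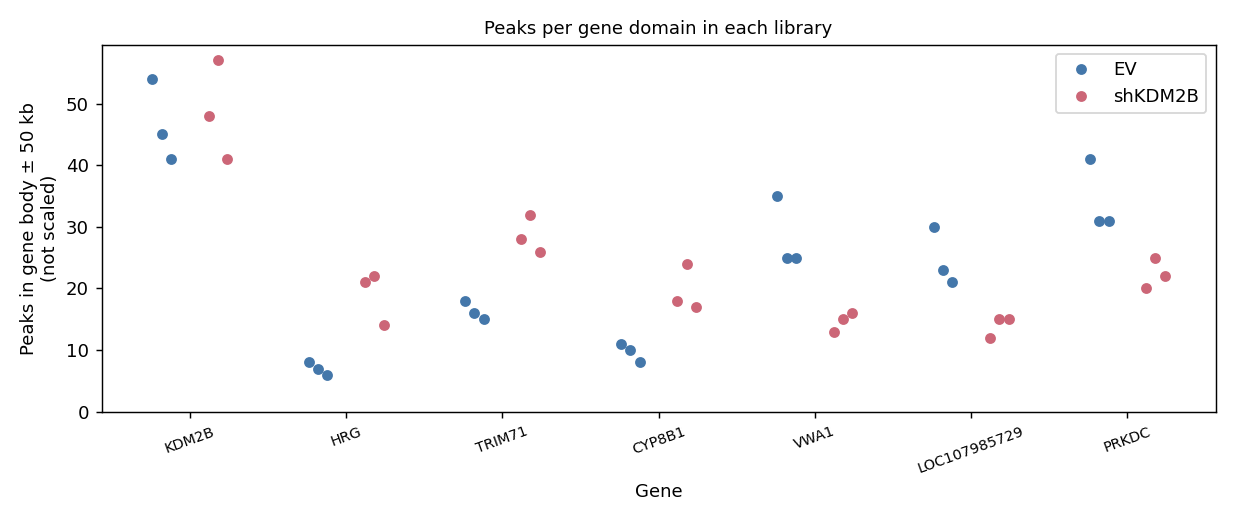
Peaks in the gene body ± 50 kb (vertical axis, not scaled) of KDM2B and of the 3 genes per direction with the smallest p, 1 point per library. At HRG the EV libraries held 6 to 8 peaks and the shKDM2B libraries 14 to 22; at VWA1 they held 25 to 35 and 13 to 16.

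For the pathways the series title names, the share of members with an open gene boundary ranged from the level of all genes, for amino acid transporters, to every member, for MYC targets. All members of the lists for MYC and MYC targets, aminoacyl-tRNA synthetases, purine and pyrimidine synthesis and housekeeping genes had a called boundary in every library (100% in EV and in shKDM2B). The share was 96.7% ± 2.89 (SD, n = 3) in EV and 98.3% ± 2.89 in shKDM2B for asparagine, aspartate, glutamate and proline metabolism, and 87.9% ± 2.62 and 86.4% for serine, glycine and one-carbon metabolism. It was 88.3% and 90.0% for the methionine cycle, transsulfuration and glutathione, 77.3% and 77.3% for amino acid transporters, and 90.0% and 91.7% for ATF4 and integrated stress response. Subunits of ncPRC1.1 reached 93.9% ± 5.25 and 100%, and other polycomb and trithorax genes 93.9% and 95.5%.

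Developmental regulators often held by polycomb had called boundaries in 62.8% ± 2.22 (SD, n = 3) of members in EV and 59.0% ± 5.88 in shKDM2B, and epithelial-mesenchymal genes in 75.8% ± 2.62 and 80.3% ± 5.25. The shares were 90.0% and 88.3% for cell cycle, 95.0% and 95.0% for hypoxia, 92.6% and 94.4% for AP-1, TEAD and YAP genes, and 95.8% and 95.8% for inflammatory and interferon genes. Among marker lists they were 92.9% and 92.9% for luminal epithelial, 76.2% and 81.0% for immune, and 50% and 59.5% for fibroblast and endothelial genes. The last had the smallest p of the 20 lists (exact permutation p = 0.1, adjusted p = 1). Members with a boundary called in 1 group only were PAX2, a developmental regulator, and GAPDH, a housekeeping gene, in EV. In shKDM2B they were BCORL1, a subunit of ncPRC1.1, the hypoxia gene LOX and the endothelial marker PECAM1. Counting both ends of the gene, GAPDH and LOX still had a called boundary in all 6 libraries, and BCORL1 had one in EV replicate 1. At each of these 5 a region called in 1 group only lay at the boundary, for example at BCORL1 (X chromosome, 129980795 to 129981210; the authors' fold 2.95 to 5.41) and LOX (chromosome 5, 122062279 to 122062760; 2.82 to 4.76). The PAX2 and GAPDH peaks did not reach the stricter threshold in all EV libraries (0 and 2 of 3). With 1 such gene at most per list and direction, none of the 20 lists passed the test against the 5792 genes called in 1 to 5 libraries (Fisher's exact test, adjusted p = 1). In that background ncPRC1.1 had 3 members and hypoxia 4, so that these tests say little on such lists.

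By peaks per domain, no list passed the test (camera), and limma called 0 members over all genes tested. Members adjusted over the list alone numbered 3 epithelial-mesenchymal genes, 1 MYC target, 1 hypoxia gene and 0 in each of the other 17 lists. The domains of the epithelial genes CDH1 (17, 16 and 15 peaks in EV against 22, 23 and 22; log2 0.45) and GRHL2 (33, 30 and 31 against 42, 55 and 37; log2 0.47) and the mesenchymal factor ZEB1 (16, 14 and 12 against 19, 22 and 16; log2 0.41) had more peaks in shKDM2B (limma, adjusted over the list alone, 0.0314 for all 3). These domains can take in neighbouring genes. No library had a called boundary of CDH1, only shKDM2B replicate 2 had one of GRHL2, and every library had one of ZEB1. More peaks in shKDM2B were also counted in the domain of the transferrin receptor gene TFRC (23, 16 and 13 against 25, 30 and 26; log2 0.64; 0.00975 by limma, adjusted over the list alone). The glycolytic regulator PFKFB3 had fewer (36, 31 and 29 against 24, 26 and 25; log2 −0.36; 0.0450 by limma, adjusted over the list alone). Under the stricter threshold the log2 changes were 0.29 for CDH1, 0.13 for GRHL2, 0.23 for ZEB1, 0.21 for TFRC and 0.02 for PFKFB3, and 0 epithelial-mesenchymal and 0 hypoxia genes passed when adjusted over the list alone. The 1 MYC list gene that passed there was BOP1, so TFRC did not. With the matched number 1 epithelial-mesenchymal, 0 hypoxia and 0 MYC list genes passed, and with the replicate block 0 hypoxia genes. Epithelial-mesenchymal genes had 15 of 22 members above 0 (median log2 0.07; camera adjusted p = 0.266), and developmental regulators 17 of 25 (median log2 0.16; adjusted p = 0.457), with HOXA13 at log2 0.42 and PAX9 at log2 −0.41.

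The 2 members with the smallest p of each metabolic or stress response list did not pass the test over all genes. In serine metabolism they were PSAT1, an enzyme of serine synthesis (log2 −1.02 ± 0.36 SE, n = 3 per group), and GNMT (log2 −0.43), and in asparagine and proline metabolism ASNS, asparagine synthetase (log2 −0.44), and PYCR1 (log2 −0.50). In the methionine cycle and glutathione list they were AMD1 (log2 −0.54) and GCLC (log2 0.23). Among transporters they were SLC38A3 (log2 −0.38) and SLC36A1 (log2 0.32). For tRNA synthetases they were IARS1 (log2 −0.47) and AARS1 (log2 −0.26). Among stress response genes they were TRIB3 (log2 −0.39) and CEBPG (log2 −0.26). None of their lists passed the test: 8 of 20 members were above 0 for asparagine, aspartate, glutamate and proline metabolism, 12 of 22 for serine, glycine and one-carbon metabolism, 6 of 18 for the methionine cycle, 8 of 21 for transporters, 8 of 20 for tRNA synthetases and 8 of 20 for ATF4 and integrated stress response (camera adjusted p from 0.539 to 0.912). MYC itself had 15, 14 and 12 against 18, 28 and 16 peaks (log2 0.52; limma adjusted p = 0.209), and 8 of 20 members of its list were above 0 (camera adjusted p = 0.912). Of ncPRC1.1 subunits, 2 of 11 were above 0, with USP7 (log2 −0.22) and YAF2 (log2 −0.25) the lowest p (camera adjusted p = 0.539). Their direction turned under the stricter threshold, where 7 of 11 were above 0 (median log2 0.03). Of other polycomb genes, 11 of 22 were above 0, with PCGF3 at log2 −0.28 and EZH2 at log2 0.44 (adjusted p = 0.912). Purine and pyrimidine synthesis had 9 of 20 above 0, with PRPS2 at log2 −0.72 and RRM2 at log2 −0.30, and housekeeping genes 3 of 14, with YWHAZ at log2 0.24 (both adjusted p = 0.539).

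For the remaining lists the members above 0 were 10 of 18 for cell cycle, 12 of 20 for hypoxia, 11 of 18 for AP-1, TEAD and YAP genes, 14 of 23 for inflammatory and interferon genes, 6 of 14 for luminal epithelial, 8 of 14 for immune and 6 of 14 for fibroblast and endothelial markers (camera adjusted p from 0.539 to 0.912). Their members with the smallest p were PLK1 (log2 −0.32) and CDK2 (log2 −0.16), PFKFB3 and SLC2A1 (log2 0.29), TEAD4 (log2 −0.37) and FOSL2 (log2 0.25), OAS1 (log2 0.47) and RIGI (log2 0.26), KRT19 (log2 0.22) and KRT18 (log2 0.24), CD3D (log2 0.48) and SPI1 (log2 −0.34), and ACTA2 (log2 0.39) and PDGFRA (log2 0.33), in the same order. With an estimated correlation none of the 20 lists passed either (adjusted p from 0.829 to 0.919). The median and the mean differed in sign for transporters, asparagine metabolism, MYC targets, fibroblast and endothelial markers and serine metabolism; the test took the sign of the median in all of these but the fibroblast and endothelial markers. With the matched number of peaks, epithelial-mesenchymal genes passed (16 of 22 above 0; camera adjusted p = 0.0356), but not with an estimated correlation (adjusted p = 0.527).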

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

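The tests with masked chromosome starts, with the stricter threshold and matched number together, and with libraries left out under the stricter threshold or the masking were chosen after the results were seen. Of the alternatives to the results that answer a comparison, 136 kept the direction and the side of the threshold, or stayed within 1.5 times a count, 29 moved and 3 reversed. Permutation tests of 3 against 3 cannot fall under 0.1, so for covered length, similarity and boundary share only the direction could change, and it did not. For similarity, another split exceeded the real one when any library other than EV replicate 3 was left out. Those splits have unequal sides and are not like the splits of 3 against 3. The difference in peak number (shKDM2B minus EV) reversed to −2361 under the stricter threshold, and leaving out single libraries gave −9929 to 16764, negative without EV replicate 3 (−3828) and shKDM2B replicate 2 (−9929). Both thresholds at once left 1402 EV-only regions, 1471 shKDM2B-only regions and 103 genes with a boundary called in 1 group only, fewer by construction. Leaving out a library, which also loosens the requirement, gave 4239 to 6747 EV-only regions, 6029 to 8825 shKDM2B-only regions and 460 to 554 genes. With the stricter threshold, matched number and masked starts, leaving out a library gave 3396 to 5198, 5007 to 7076 and 322 to 465. Genes with more and with fewer peaks per domain, 0 and 0 by limma, became 2 and 7 under the stricter threshold, 2 and 2 when its lists were also matched, and 16 and 4 with masked starts. Leaving out a library gave 0 to 46 and 0 to 73 under the stricter threshold (46 and 73 without EV replicate 1) and 0 to 104 and 0 to 171 with masked starts (104 and 171 without shKDM2B replicate 2, 1 and 1 without shKDM2B replicate 3); the cause was not tested. With no scaling limma also called 0 genes (809 with more and 544 with fewer at an unadjusted p under 0.05). The matched number gave 1 gene list by domain (epithelial-mesenchymal genes, adjusted p = 0.0356 by camera, and adjusted p = 0.527 with an estimated correlation). The log2 change of KDM2B reversed to −0.10 under the stricter threshold, −0.19 when also matched and −0.021 without shKDM2B replicate 2 (leaving out single libraries gave −0.021 to 0.11). For single named genes and regions, 417 alternatives kept the result, 28 ended a call (all at gene boundaries, with the summit rule or the 2.5 kb window), 7 raised a domain past the threshold (6 of them with masked starts) and 3 reversed. Much of this was fixed in advance. Leaving out a library cannot end a boundary call, and the stricter and matched lists keep peaks as strong as those of the named regions (30 alternatives). For peaks per domain, 95 kept only the sign, since no named domain passed the threshold to begin with. Same-numbered libraries correlated at −0.19 to 0.32 and others at −0.63 to 0.46 across genes. These values show no pairing by number, but 3 same-numbered pairs cannot exclude one. With the number as a block limma called 0 genes (lowest adjusted p 0.0839, with 1403 with more and 1413 with fewer at an unadjusted p under 0.05). An overlap of 50% removed no region from any library and so tests nothing, and the CpG and motif alternatives were not run. Read depth is unknown, so how it limits a call in EV replicate 1 is known only from the values without that library.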

Other observations

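The tests of the chromosome starts, of 1 library behind chromosome 3, of unequal lists, of EV replicate 1, of the splits other than with masked starts, and of changed regions in gene domains were chosen after their results were seen, and so were the genes named here.

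Domains with the most regions called only in shKDM2B were those of PTK2, RBFOX3, DLG1 and SRGAP3. PTK2, the focal adhesion kinase gene (chromosome 8, 140657900 to 141002079), held 12 such regions among the 109 called in 1 to 5 libraries and 0 EV-only ones (Fisher's exact test, adjusted p = 0.688). RBFOX3 held 10 of 205, DLG1 8 of 56, SRGAP3 8 of 118, SHANK2 7 of 166 and the transcription factor gene RUNX1 6 of 32, and none passed the test (509 genes at an unadjusted p under 0.05). Regions called only in EV were most concentrated at POM121L2 and its neighbour LOC105375107 on chromosome 6 (5 of 11 regions; adjusted p = 0.00582), the only 2 genes past the threshold. ARID3A held 6 EV-only regions of 33 (adjusted p = 0.0866). Among list members, CDH1, TGFBI, NCL, HERPUD1 and PHC2 each had 3 shKDM2B-only regions and 0 EV-only ones, PYCR1 had 3 EV-only ones and 0 shKDM2B-only ones, and MYC and ATF4 had 0 of either.

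Epithelial-mesenchymal genes had the smallest p of the 20 lists when changed regions were counted in domains: 15 of 301 regions (4.98%) were called only in shKDM2B, against 2.65% in other domains (Fisher's exact test, p = 0.0183, adjusted p = 0.732). The list misses the test. Strong shKDM2B-only regions outside the rule for named genes lay near CSF1 (chromosome 1, 109892261 to 109893144; the authors' fold 4.31 to 5.70), TGFBI (chromosome 5, 135996515 to 135997038; 4.52 to 6.38) and SLC6A6, the taurine transporter gene (chromosome 3, 14363757 to 14364382; 3.798 to 5.93), and in the body of ETS1 (chromosome 11, 128574386 to 128575418; 6.65 to 13.3).

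With the chromosome starts masked, limma called 16 genes with more peaks in shKDM2B, and 11 of them lay on chromosome 3, which holds 1052 of the 18489 genes tested. They were HRG and its neighbour FETUB, TRIM71, CNOT10, STT3B, OSBPL10, CYP8B1, ACKR2, DLG1, SENP5 and SPINK8. STT3B had 14, 10 and 8 peaks in EV and 23, 20 and 22 in shKDM2B (log2 1.01), and CNOT10 had 13, 13 and 11 against 28, 24 and 21 (log2 0.93). STT3B and OSBPL10, CNOT10 and TRIM71, ACKR2 and CYP8B1, and HRG and FETUB are neighbours whose domains overlap. Fewer peaks were counted at PRKDC and at VWA1, LOC107985729 and ATAD3B, which lie close together on chromosome 1 with domains that overlap. At each of these genes the groups did not overlap, and without masking the log2 change of HRG stayed at 1.24 to 1.503 and that of VWA1 at −1.03 to −0.87 when any library was left out. Under the stricter threshold the log2 change of HRG was 0.31, of TRIM71 0.26, of OSBPL10 0.20 and of NCOA6 −0.003. The number of calls varied with the library left out, with fewer libraries to test: with masked starts limma called 0 genes without EV replicate 1, 2 or 3 or shKDM2B replicate 1 (2018 to 2571 at an unadjusted p under 0.05), 1 and 1 without shKDM2B replicate 3, and 104 and 171 without shKDM2B replicate 2.

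In the splits of the 6 libraries into 3 and 3, a result as large as the real one came from 1 of 10 splits for regions called in 1 group only (8261, highest other 3882) and from 1 of 10 for gene boundaries (312, highest other 154). For genes by peaks per domain the real count was 0, so all 10 of 10 splits were as large by construction (highest other 111); at an unadjusted p under 0.05 the real groups gave 2583 genes and the other splits at most 1483. It came from 2 of 10 under the stricter threshold (9, highest other 109; unadjusted 2837 against at most 1295) and from 2 of 10 with masked starts (20, highest other 29). With 10 splits, none of these shares can fall under 0.05. The split with 111 and 109 genes sets EV replicates 1 and 3 and shKDM2B replicate 1 apart, the 3 libraries with no peaks at the start of chromosome 22, and at the authors' threshold it called 0 genes once the starts were masked. Its 111 calls at that threshold thus follow the missing stretches, a structure of the lists that is not the groups. The masking was not run for its 109 calls under the stricter threshold, which are several times the real 9 and point to a structure of the samples or lists other than the groups.

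Some libraries held no peaks over the start of a chromosome where the others held many. On chromosome 14 EV replicate 1 had none before 31457156, on chromosome 15 EV replicates 2 and 3 and shKDM2B replicates 1 and 3 had none before 33584886, and on chromosome 22 EV replicates 1 and 3 and shKDM2B replicate 1 had none before 25166784, while the other libraries held 397 to 874 peaks there. A knockdown difference is argued against, since libraries of both groups lacked the peaks on 2 of the 3 chromosomes. Each start lay near a whole multiple of 2 to the power of 20 bases, nearer than a random place would in 5.81% of cases or fewer, so processing or transfer of the data in blocks is a candidate explanation. The stretches touch 159, 86 and 136 genes. If the lists are incomplete there, the missing peaks of those libraries carry no information on accessibility.

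Chromosome 3 carried an excess of shKDM2B-only regions and X an excess of EV-only ones. Each library was left out in turn to ask whether a single one was the source on chromosome 3. With the stricter threshold and matched number, its shKDM2B-only share stayed above that elsewhere without each library. The highest Fisher's exact p was 4.73e-06 (67.5% against 59.5% elsewhere, without shKDM2B replicate 2). Regions are the unit of that test, so its p does not measure the spread between libraries. Leaving out a library also loosens the requirement and keeps the regions counted with all 6. These values therefore cannot exclude a single library as the source. A difference in copy number between the cultures, a biological difference that may arise between lines carrying different constructs, would also raise the strength of peaks shared by all libraries. Among regions called in all 6, the mean percentile rank of chromosome 3 was 0.454 higher in shKDM2B (50.3 ± 0.37 against 49.9 ± 0.11, SD, n = 3; exact permutation p = 0.2, smallest possible 0.1), and that of X was −0.444 (shKDM2B minus EV; exact permutation p = 0.8). The rank rose more on chromosomes 13 (0.509), 21 (1.25) and 22 (1.24). Their shKDM2B-only shares were 44.5%, 55.2% and 60.3%, against 58.6% over all chromosomes. With groups that overlap on chromosome 3 and on X and 3 libraries each, neither of these 2 shifts excludes or shows a copy number difference. An effect of KDM2B on chromosome 3 or X was not tested apart from it.

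More regions were called only in shKDM2B than only in EV, at a ratio of 1.42. Weak peaks and unequal list lengths are a candidate explanation, and the ratio was 1.18 with the stricter threshold, 1.28 with the matched number, 1.12 with the summit rule and 1.049 with both thresholds. With the stricter threshold, matched number and masked starts it was 1.51, and 1.02 without EV replicate 1. The ratio thus fell under some settings and rose under another. These values cannot tell weak peaks or unequal lists from a real excess. EV replicate 1, with its low implied background, is another candidate: without it the ratio at the authors' threshold was 1.23. It was 1.35 without EV replicate 2 and 0.931 without EV replicate 3. Ratios of 2 libraries against 3 are not like the 1.42 of 3 against 3, since the requirement loosens unequally for the EV-only and shKDM2B-only counts. In the stricter, matched and masked lists the ratio stayed above 1 without each library (1.02 to 1.51; 1.40 without EV replicate 3), so only its direction at the authors' threshold turned with 1 library, and a gain of open regions after the knockdown stays a hypothesis.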
